A study of Mus musculus with 12 samples.

How the data were processed

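The deposited table covered 12 libraries of mouse forebrain microglia, made of 4 groups of 3: H3K27ac chromatin immunoprecipitation (ChIP) from wild-type mice, the same from Nlrp3 knockout mice, and the input chromatin of each genotype. H3K27ac, acetylation of lysine 27 on histone H3, marks active promoters and enhancers. Per the labels' protocols, CD11b-positive cells were isolated from dissociated, myelin-depleted brain with magnetic beads, fixed nuclei were sonicated, and 1 antibody serum was used for all immunoprecipitations. Groups came from the genotype, antibody and title labels. The labels do not state the sex of the mice or whether the replicates of a group are separate animals. Wild-type replicate 1 alone lacked tags at Y-linked promoters, so it did not share its source with replicates 2 and 3. Every knockout library held such tags. Sex was therefore probably unbalanced between genotypes, and the main fits had no covariate for it. For the other libraries the spread that p-values measure may be technical.

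The values used were raw tag counts that the authors deposited, 1 per library and window, with no normalization. Per the file headers, tags were counted with HOMER's annotatePeaks.pl on mm10, unadjusted, in 67822 windows of 1000 bp centred on merged sites taken from a directory named ATAC. Per the file headers, each window also carries the names of the site lists it was merged from, 1 for wild type and 1 for the knockout. Of these windows 51215 stood in both lists, 11060 in the wild-type list alone and 5547 in the knockout list alone. The submitters' processing notes name HOMER, DESeq2 and mm10. The aligner, duplicate handling, tag length, the caller behind the site lists and the tool versions are not given in the sources used here. A second table, scaled per the file headers to an equal total per library, was not used because it holds the same counts times 1 factor per library. Windows were fixed by accessible sites, so H3K27ac elsewhere was not measured, and 14856 windows overlapped the one before them and share tags with it.

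The H3K27ac libraries held 3726550 to 5028129 tags, of which 39.1% to 46.1% lay in windows, with a median of 12 to 16 tags per window. The input libraries held 3287009 to 6961590 tags, 8.31% to 9.32% of them in windows, with a median of 2 to 5 per window. ChIP over input was computed as the ratio of group mean counts scaled to equal totals (CPM), with 0.5 added to both. No molecular identifiers are described, so intervals and floors from tag counts cover counting error only.

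Knockout and wild type were compared with edgeR 4.0.16 (R 4.3.3): trimmed mean of M values (TMM) normalization, filterByExpr, a quasi-likelihood fit of 3 against 3 libraries without covariates, and Benjamini-Hochberg adjustment with a threshold of 0.05 ("called" below means past that threshold). The fit ran on single windows, on sums over the windows within 100 kb of a gene's transcription start site (TSS), with each window given to the nearest TSS named in the table, and on the input libraries alone. The filter kept 40370 windows, 12148 of 15879 genes and 307 input windows. Standard errors are the fitted log2 fold change over the square root of F. Levels are CPM given as mean ± SD, where the total is the TMM-normalized sum of tags over the windows or genes that the filter kept. They are therefore higher than CPM on all tags of a library, the scale used for ChIP over input. A promoter window lay within 1 kb of a TSS. Of the windows, 63386 lay within 100 kb of a TSS and 117 had no gene. A fold against a group at 0 was computed with 3 tags over that group as its floor.

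Gene lists were tested with camera (limma 3.58.1) on the per-gene fit with a preset correlation of 0.01, adjusted over 24 lists. The lists were glutamine and glutamate metabolism, the TCA cycle and ketoglutarate, glycolysis and the pentose phosphate pathway, oxidative phosphorylation, ketoglutarate-dependent dioxygenases, histone acetylation machinery, lipid and cholesterol metabolism, inflammasome and IL-1, NF-kB cytokines, interferon response, TGF-beta pathway, homeostatic microglia, disease-associated microglia, phagocytosis and lysosome, Alzheimer's disease risk genes, proliferation, dissociation-induced immediate early genes, and markers of neurons, astrocytes, oligodendrocytes, endothelial and mural cells, border macrophages, monocytes and neutrophils, and lymphocytes. Nlrp3, the targeted gene, was put in none of them. Of 830 listed symbols 733 had a window, 3 of them through an alias. Gene coordinates came from a RefSeq table of the same build.

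Windows were named in the text if called, at or above the median abundance of tested windows, and with all 3 libraries of 1 genotype above all 3 of the other, up to 10 per direction by fold and 1 per gene. In each list, up to 3 called genes per direction were named, or the gene with the smallest p where none was called. Fixed in addition were Nlrp3, Slc1a3, Glul, Glud1, Slc1a5, Il1b, Apoe, Trem2, Clec7a, Spp1, P2ry12, Tmem119, Sall1 and Cx3cr1. Groups, tests, lists, this rule and most alternatives were chosen before the data were examined. Some items that the rule covers are not reported here. Names outside the rule are said to be chosen afterwards.

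The alternatives were DESeq2 size factors in edgeR, total tags without TMM, loess offsets, DESeq2 1.42.0, no abundance filter, a replicate block, each library left out in turn, other distances to the TSS, a minimum fold of 1.5, other gene list tests and other flank widths. Added after seeing the data were fits without overlapping windows, fits restricted to assembled chromosomes with more ChIP than input tags, fits without chromosomes X and Y, and Slc1a3 without its upstream window. A planned motif test was not run because no genome sequence was used here.

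The scripts were tested on simulated counts drawn from the real means and dispersions. Among 40370 simulated windows, 12 of 100 changed by 2-fold and 46 of 100 changed by 4-fold were called, with 2 false calls. Among 12148 simulated genes, 35 of 100 changed by 2-fold and 77 of 100 changed by 4-fold were called, with 4 false calls. For 307 simulated input windows the counts were 16 of 20 and 19 of 20, with 0 false calls. A list of 40 simulated genes shifted by 0.3 on the log2 scale had an adjusted p of 6.27e-04 by camera, and 0 of the other lists were called. These genes were drawn independently and all shifted the same way. The real lists held 7 to 54 tested genes, with estimated correlations up to 0.118, so recovery for small or correlated lists was not tested.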

Results

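Microglia, the resident macrophages of the brain, were profiled for H3K27ac in wild-type mice and in mice lacking Nlrp3, the sensor protein of an inflammasome that activates caspase-1 and IL-1 beta release. The series title names glutamine breakdown driven by NLRP3 in Alzheimer's disease microglia, and the labels set knockout against wild-type mice. Each genotype had 3 H3K27ac and 3 input libraries. Total tags in wild-type replicates 1, 2 and 3 were 3726550, 4492763 and 4233044, and in knockout replicates 4531757, 5028129 and 4926729. H3K27ac was concentrated at promoters: promoter windows had a median of 5.45 times the input CPM in wild type and 5.99 times in the knockout, against 2.32 and 2.51 times in distal windows. Promoters of homeostatic microglia genes stood at a median of 9.42 times input in wild type and 11.4 times in the knockout. Promoters in the 7 lists of markers of other cells stood lower, from 0.817 times (lymphocytes) to 2.22 times (astrocytes) in wild type and from 0.786 times (lymphocytes) to 3.47 times (monocytes and neutrophils) in the knockout. Libraries of 1 genotype correlated across windows with r of 0.702 to 0.782 and libraries of different genotypes with r of 0.651 to 0.796. The first principal component (31.2% of variance) set wild-type replicate 3 apart and the second (23.2%) set knockout replicate 3 apart. Promoter windows of the Y-linked genes Ddx3y, Uty and Eif2s3y together held 0 tags in wild-type replicate 1, in H3K27ac as in input, and 183 to 239 H3K27ac tags in each of the other 5 libraries. Its input tags on chromosome X were 1.035% of those on chromosomes 1 to 19, against 0.796% to 0.860% in the others.

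The targeted gene was examined first. In the more affected Nlrp3 promoter window tags were almost gone in the knockout, in H3K27ac as in input, and in the neighbouring promoter window they were lower. In the window at chromosome 11, 59542134 to 59543134 (mm10), 52 bp from an annotated Nlrp3 TSS, the wild-type libraries held 180, 180 and 195 tags and the knockout libraries 1, 0 and 16. The level went from 108 ± 4.78 to 3.13 ± 4.99 CPM (mean ± SD, n = 3 per group), a log2 fold change of −5.19 (SE 0.50, edgeR quasi-likelihood adjusted p = 4.88e-06). The neighbouring promoter window at 59541020 to 59542020 fell by 2.31 on the log2 scale (SE 0.36, edgeR adjusted p = 0.00338), from 138, 91 and 119 tags to 17, 20 and 43. Over all Nlrp3 windows the level fell by 1.65 on the log2 scale (SE 0.17, edgeR adjusted p = 2.15e-06), from 309 ± 47.5 to 98.3 ± 12.5. The other 5 tested Nlrp3 windows were not called; the nearest, in an intron at 59543688 to 59544688, had a log2 fold change of −0.998 and an edgeR adjusted p of 0.998. Input tags in the TSS window were 10, 5 and 3 in wild type and 0 in each knockout library. In the neighbouring promoter window they were 4, 9 and 3 against 2, 1 and 0, and in that intronic window 9, 5 and 1 against 0, 0 and 2. Upstream, at 59538040 to 59539040, input tags were 4, 6 and 9 in wild type and 11, 6 and 7 in the knockout. With DESeq2 the TSS window was no longer called (−5.12, adjusted p = 0.157), without knockout replicate 3 its log2 fold change was −8.46, and within 1 kb of a TSS that of the gene was −3.40. The neighbouring window lost its edgeR call without wild-type replicate 1, knockout replicate 1 or knockout replicate 2, which left 1 called Nlrp3 window in each case.

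**Figure D1:**
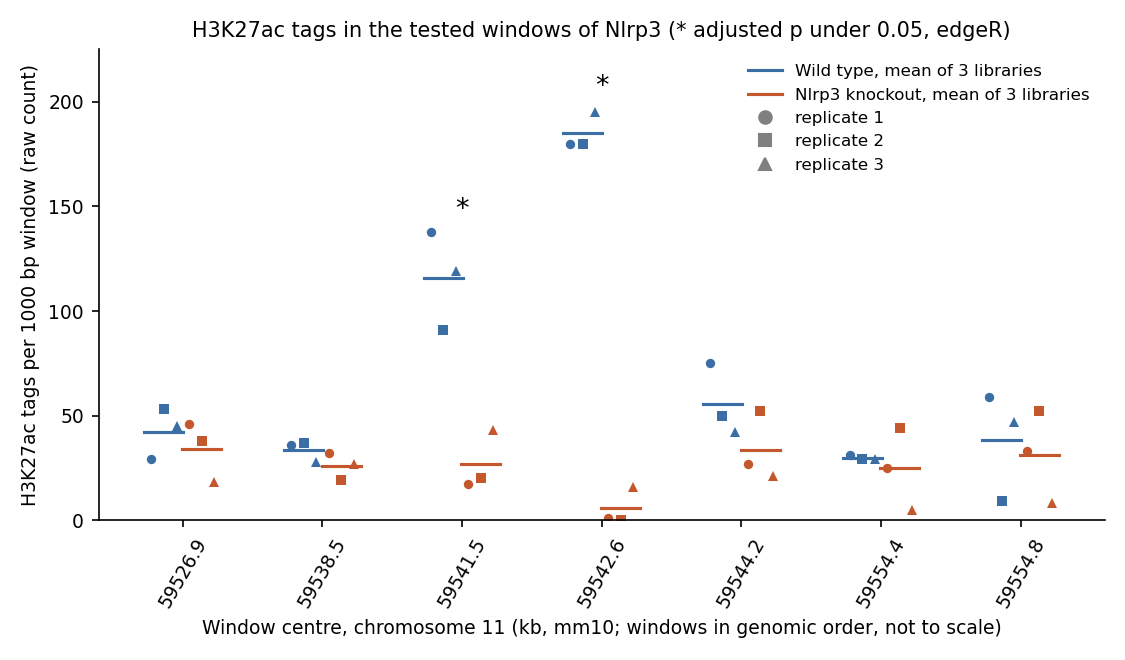
H3K27ac tags per 1000 bp window in the 7 tested windows of Nlrp3 (y axis, raw tags; x axis, window centre in kb on chromosome 11, in order but not to scale), with 1 point per library and a bar for each group mean of 3. In the window at the TSS, with the lowest knockout tags, the wild-type libraries lie between 180 and 195 tags and the knockout libraries between 0 and 16.

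Across the genome, of 40370 windows 24 were called, 10 higher and 14 lower in the knockout, and 1894 (4.69%) had an unadjusted p under 0.05. In all 24 the groups did not overlap, as they did not in 4393 (10.9%) of tested windows against the 10% that chance gives for 3 against 3. A window at −91066 bp from the TSS of Slc1a3, which encodes the glutamate and aspartate transporter GLAST, rose by 3.31 on the log2 scale (SE 0.49, edgeR adjusted p = 0.00208) at chromosome 15, 8801373 to 8802373. Its knockout replicates were far apart, at 434, 55 and 458 tags against 13, 36 and 37 in wild type. A window in an intron of Me2, a mitochondrial malic enzyme that turns malate into pyruvate, rose by 3.04 (SE 0.48, edgeR adjusted p = 0.00485), from 4.04 ± 2.33 to 34.1 ± 3.50 CPM (chromosome 18, 73812300 to 73813300). An intronic window of Eps8, a regulator of actin filament capping and bundling, rose by 2.78 (SE 0.46, edgeR adjusted p = 0.00751) at chromosome 6, 137574957 to 137575957. The remaining windows that rose under the naming rule lay nearest Ropn1l (3.61), Rbm5 (3.06) and the long non-coding RNA Fhad1os1 (2.98).

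Besides Nlrp3, named windows that fell lay nearest Zfp467, Fblim1, 4930481A15Rik, Tnfrsf14, Strap and G530011O06Rik. The promoter window of Fblim1, which encodes a filamin-binding adaptor of cell adhesions, fell by 2.91 (SE 0.50, edgeR adjusted p = 0.00919), from 117, 111 and 87 tags to 2, 41 and 7 (chromosome 4, 141605590 to 141606590). An intronic window of the zinc finger gene Zfp467 fell by 3.32 and a window nearest Tnfrsf14, a receptor of the tumour necrosis factor receptor family, by 2.69. The windows nearest 4930481A15Rik, Strap and G530011O06Rik had log2 fold changes of −2.71, −2.29 and −1.36. Outside the naming rule, and singled out after their values were seen, 2 intronic windows of Rnf157 held 0 tags in every knockout library and were at least 50.02-fold and 40.7-fold lower, and a window in an intron of Gaa, the lysosomal acid alpha-glucosidase, held 0 tags in every wild-type library and was at least 28.7-fold higher. Leaving out wild-type replicate 1 or 2 or knockout replicate 1 or 2 brought the 24 calls to 12 (9 higher, 3 lower), 10 (7 and 3), 13 (5 and 8) and 11 (6 and 5), and DESeq2 made 68 calls, 16 of them among the 24. Of the 13 named windows, the upstream window of Slc1a3 and the TSS window of Nlrp3 alone were called with any library left out, while DESeq2 called neither and left 7 of the 13 uncalled in all; the Fblim1 window had a log2 fold change of −4.65 without knockout replicate 2 and that of 4930481A15Rik −4.25 without knockout replicate 3.

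**Figure D2:**
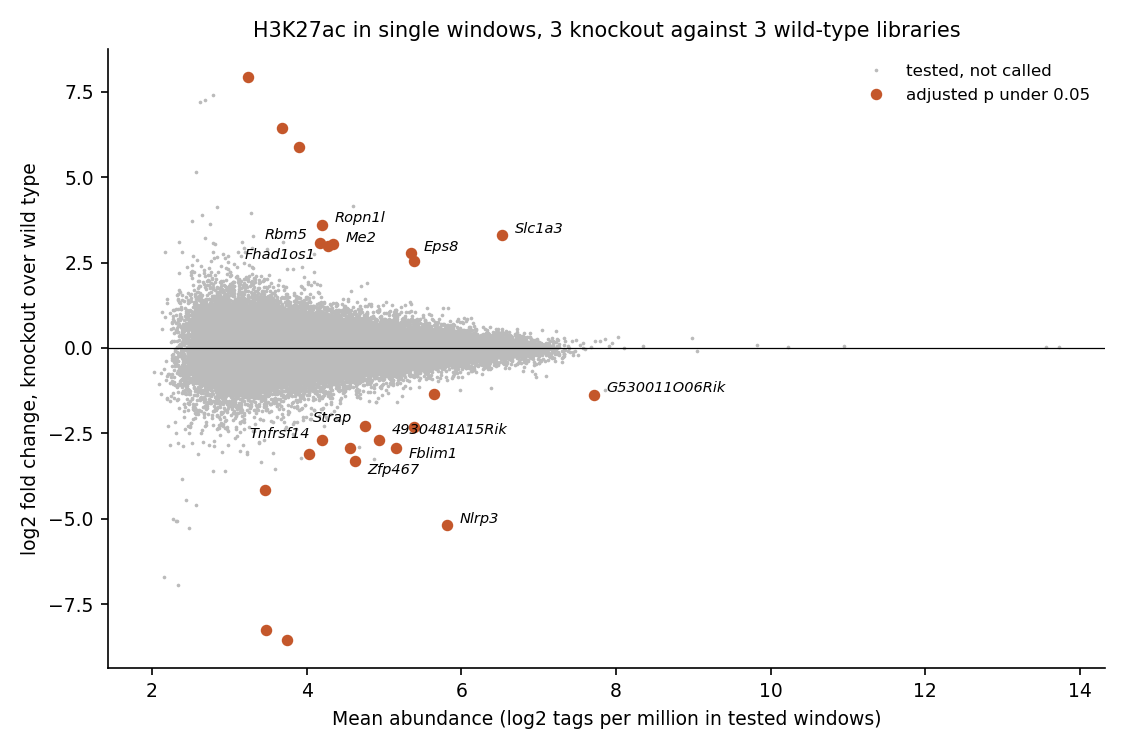
Log2 fold change of H3K27ac, knockout over wild type (y axis), against mean abundance in log2 CPM (x axis) for 40370 windows, 1 point each. The 24 called windows are the large points, 10 above and 14 below 0, and named windows carry the symbol of the nearest gene.

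Promoter and distal windows were compared to see where the differences lay. The 4 called promoter windows all fell: both Nlrp3 promoter windows and those of Fblim1 and 4930481A15Rik. Distal windows held the other 20 calls, 10 in each direction. The called share was 4 of 13774 in promoter windows and 20 of 26596 in distal windows, an odds ratio of 0.386 (95% interval 0.0959 to 1.15, 2-sided Fisher's exact p = 0.0850), and the direction did not differ by the same exact test (p = 0.114). Neighbouring windows are not independent, so these p-values are approximate; with DESeq2's 68 calls the odds ratio was 0.456 (Fisher's exact p = 0.00987). Without wild-type replicate 1, knockout replicate 1 or knockout replicate 3 it was 0.185, 0.170 and 0.774, with 1, 1 and 8 called promoter windows.

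Summed per gene, H3K27ac changed at 25 of 12148 genes, 7 higher and 18 lower in the knockout, with 701 (5.77%) at an unadjusted p under 0.05. Slc1a3 rose by 0.69 on the log2 scale (SE 0.14, edgeR adjusted p = 0.0248), from 541 ± 12.3 to 875 ± 273 CPM (n = 3 per group). Cd300lf, an inhibitory receptor of myeloid cells, rose by 1.29 (SE 0.24, edgeR adjusted p = 0.0163), from 47.4 ± 7.95 to 116 ± 11.8. Of the called genes outside the naming rule, 4 were chosen after their values were seen: Eps8 rose by 1.21 (SE 0.15), while Zfp467 fell by 2.00 and Mpc1, a subunit of the mitochondrial pyruvate carrier, fell by 1.26 (SE 0.26, edgeR adjusted p = 0.0224), from 117 ± 32.8 to 48.9 ± 7.66. Cd300c2, a neighbour of Cd300lf in the same receptor family, fell by 0.97 (SE 0.21, edgeR adjusted p = 0.0468). The microglial genes fixed in advance showed no call: log2 fold changes were 0.06 for P2ry12, 0.15 for Tmem119, 0.13 for Cx3cr1, −0.01 for Sall1, 0.11 for Apoe, 0.03 for Trem2, −0.81 for Clec7a, −0.47 for Spp1 and −0.04 for Il1b, with edgeR adjusted p from 0.931 to 1.00. Limited to windows within 1 kb of a TSS the test called 1 gene, Nlrp3, and Zfp467 had a log2 fold change of −0.59. Leaving out wild-type replicates 1 or 2 brought the 25 calls to 8 and 12, leaving out knockout replicates 1 or 3 to 15 and 14, and total-tag scaling to 16, while Eps8, Zfp467 and Nlrp3 were called with any library left out, Cd300lf and Mpc1 lost their calls without any of 4 libraries and Cd300c2 without any of the 6.

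At Slc1a3 the windows were set side by side for each library. The gene lies at chromosome 15, 8634124 to 8710807. In an intronic window at 8706400 to 8707400, chosen after its values were seen, knockout replicates 1, 2 and 3 held 128, 0 and 120 tags and wild-type replicates 9, 3 and 0 (log2 fold change 4.16, SE 0.93, edgeR adjusted p = 0.141). In the promoter window at 8710294 to 8711294 the knockout held 123, 19 and 120 tags and wild type 25, 15 and 87 (0.90, edgeR adjusted p = 0.998). A window over the end of the gene, in the 3' untranslated region at 8635085 to 8636085, held 157, 175 and 139 tags in the knockout and 148, 177 and 133 in wild type (−0.18, edgeR adjusted p = 0.998). The per-gene call of Slc1a3 ended with DESeq2 (0.69, adjusted p = 0.569), with total-tag scaling (0.67, edgeR adjusted p = 0.0595), within 1 kb of a TSS (0.95, edgeR adjusted p = 1.00) and without the window at −91066 bp (0.42, edgeR adjusted p = 0.273, an alternative chosen after seeing the data). It also ended when wild-type replicate 1, 2 or 3 or knockout replicate 1 or 3 was left out (log2 fold changes 0.71, 0.69, 0.67, 0.61 and 0.50, edgeR adjusted p 0.0973, 0.173, 0.163, 0.286 and 0.231).

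**Figure D3:**
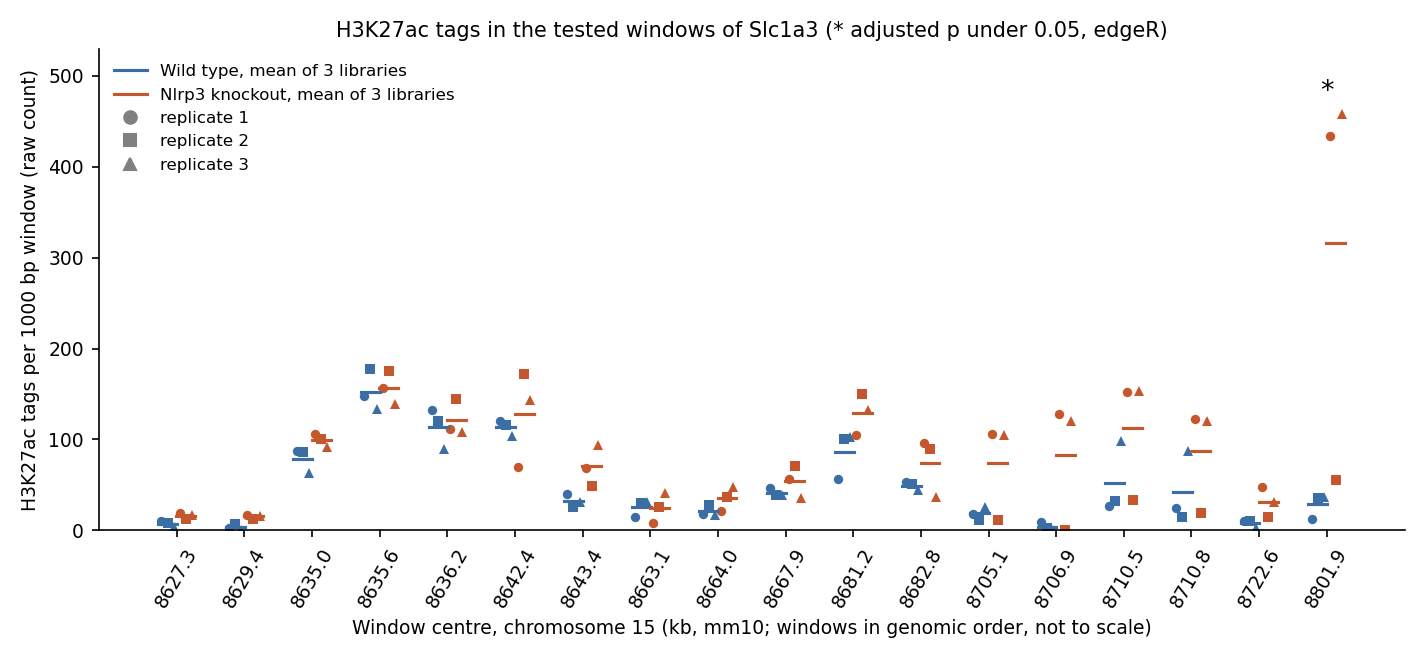
H3K27ac tags per 1000 bp window in the tested windows of Slc1a3 (y axis, raw tags; x axis, window centre in kb on chromosome 15, in order but not to scale), with 1 point per library and a bar for each group mean of 3. In the window furthest upstream knockout replicates 1 and 3 lie at 434 and 458 tags, knockout replicate 2 at 55 and the wild-type libraries between 13 and 37.

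No metabolic gene list was called. Of all 24 lists camera called 0, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.966; with an estimated correlation there were also 0 calls. Another set test, fry, called 0 lists, with 1 at an unadjusted p under 0.05, and its mixed-direction form called 0, with 2 at an unadjusted p under 0.05. For glutamine and glutamate metabolism, the subject of the series title, 35 of 44 genes were tested, 16 with a positive fold change, and the median log2 fold change was −0.02. Slc1a3 was its 1 called gene, both over all genes and adjusted over the list alone. The glutamine synthetase Glul (0.14, SE 0.15) and the glutamate dehydrogenase Glud1 (0.24, SE 0.46) were not called, and the glutamine transporter gene Slc1a5 was removed by the abundance filter. For the TCA cycle and ketoglutarate list the median was 0.05, 20 of 30 tested genes had a positive fold change, and the unadjusted camera p was 0.0587 (p = 0.0983 with an estimated correlation). In it 0 genes were called over all genes and 1 adjusted over the list alone, Me2 (1.36, SE 0.37, edgeR adjusted p = 0.0331 over the list and 0.239 over all genes). Oxidative phosphorylation (43 tested, median 0.09), glycolysis and the pentose phosphate pathway (27, 0.11), ketoglutarate-dependent dioxygenases (32, 0.05), histone acetylation machinery (31, −0.0032) and lipid and cholesterol metabolism (37, −0.14) had 0 called genes, over all genes and adjusted over the list alone. Their members with the smallest p, Atp5o (−0.63), Slc2a6 (−0.78), Hif1an (1.06), Kat7 (−0.31) and Srebf2 (0.75), did not pass.

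Microglial state and inflammation lists had 1 called gene between them, Cd300lf. It belonged to phagocytosis and lysosome (54 tested, median 0.01) and was the 1 gene called there adjusted over the list alone. Homeostatic microglia (47 tested, median −0.02), disease-associated microglia (41, 0.07), Alzheimer's disease risk (27, −0.02), inflammasome and IL-1 (27, −0.08, with the targeted Nlrp3 not in the list), NF-kB cytokines (36, −0.0062), interferon response (31, 0.05), the TGF-beta pathway (21, −0.03), proliferation (18, 0.05) and dissociation-induced immediate early genes (33, −0.02) had 0 calls by either adjustment. The genes with the smallest p in these lists did not pass. Among them were C1qb, a complement component (−0.34, SE 0.13), the tetraspanin gene Cd9 (0.28, SE 0.09), Nlrc4, another inflammasome sensor (−1.24, SE 0.45), the cytokine gene Il6 (−0.41, SE 0.17) and the interferon-induced Rsad2 (2.51, SE 0.76), with edgeR adjusted p from 0.379 to 0.780. The others were Spred2 (−0.38), Ski (−0.19), Rrm1 (0.77) and Egr3 (0.61).

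No list of markers of other brain and blood cells was called. Of the astrocyte list 7 of 20 genes were tested, with a median log2 fold change of −0.15, and of the oligodendrocyte list 8 of 23, with a median of −0.22. Neuron markers (7 tested) had a median of 0.01, endothelial and mural markers (12) of 0.13, border macrophage markers (18) of 0.08 and lymphocyte markers (11) of 0.01, all with 0 calls over all genes and adjusted over the list alone. Monocyte and neutrophil markers (10 tested, median 0.03) had 0 calls over all genes and 2 adjusted over the list alone, 1 in each direction. The higher one, Itga4, an integrin subunit, had a log2 fold change of 1.30 (SE 0.42, edgeR adjusted p = 0.0274 over the list and 0.478 over all genes), and the lower one, Vamp5, of −1.28 (SE 0.42, 0.0274 and 0.508). The members with the smallest p in the other lists, Ndrg2 (−0.90), Cnp (−0.40), Snap25 (0.90), Cldn5 (−0.92), Ednrb (−0.37) and Cd79b (−1.25), did not pass. Median and camera direction had opposite signs for the glutamine and glutamate, histone acetylation, TGF-beta, border macrophage and lymphocyte lists; in the TGF-beta list (0.04) and the lymphocyte list (−0.04) the mean also had the opposite sign to the median, and in the NF-kB list the mean was 0.0046.

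**Figure D4:**
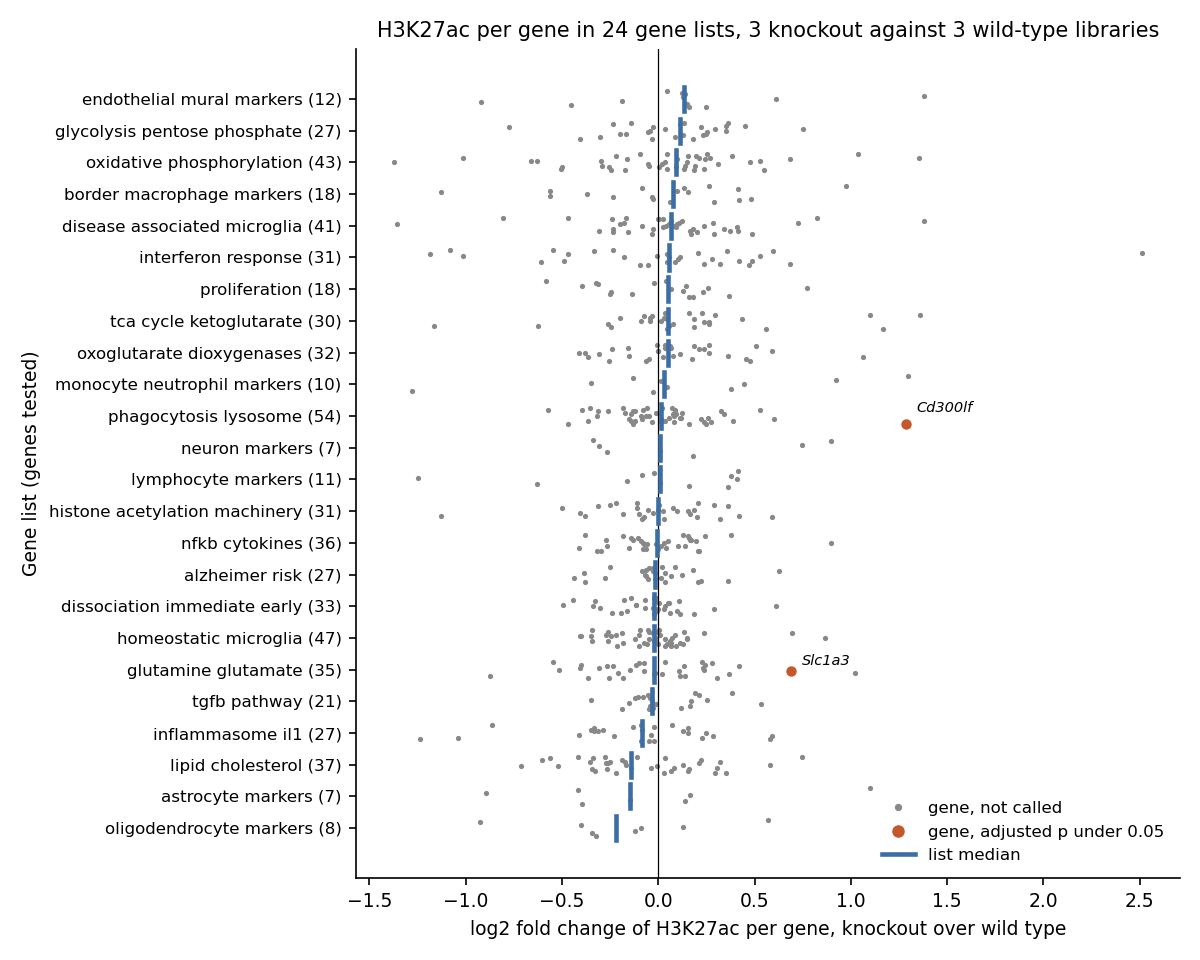
Log2 fold change of H3K27ac per gene, knockout over wild type (x axis), for the tested genes of 24 lists (y axis, number tested in parentheses), with 1 point per gene and a vertical bar at each list's median. All medians lie between −0.22 and 0.13, and Slc1a3 and Cd300lf are the called genes.

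The chromosome 11 flank of Nlrp3 was examined because sequence beside a targeted allele can come from another strain. Within 5 Mb of Nlrp3, its own windows left out, 0 of 301 tested windows were called with edgeR, 18 had an unadjusted p under 0.05 and 0 were called by DESeq2. Elsewhere edgeR called 22 of 40062, a share at which 0 calls among 301 are likely, so this count cannot show whether the flank differs. The share under 0.05 was 5.98% in the flank and 4.68% elsewhere (2-sided Fisher's exact p = 0.273). The median log2 fold change was −0.04 in the flank and 0.0048 elsewhere. Farther along the chromosome, between 109 and 119 Mb, 9 separate loci had an unadjusted p under 0.001, among them those nearest Rnf157 and Gaa.

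**Figure D5:**
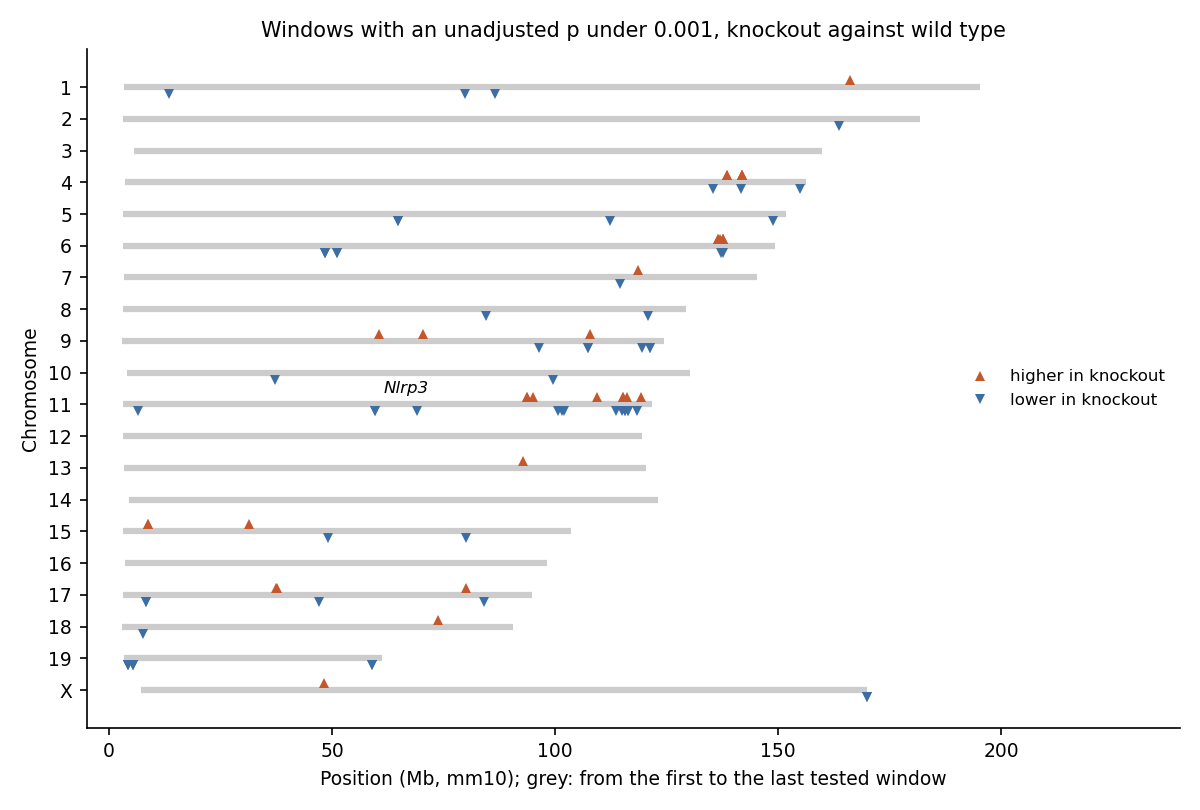
Positions of the windows with an unadjusted p under 0.001 (x axis, Mb on mm10; y axis, chromosome), with upward triangles for windows higher in the knockout and downward triangles for lower ones. Around Nlrp3 at 59.5 Mb on chromosome 11 no window other than those of Nlrp3 is marked within 5 Mb, and 9 loci lie between 109 and 119 Mb.

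Input libraries measured background in the same windows, but the abundance filter kept only 307 of 67822, many of them on unplaced sequence. A group of 6 satellite windows on chromosome 2 held 33.5% to 34.3% of window tags in wild-type input and 37.0% to 39.9% in knockout input. Background at most H3K27ac sites was therefore not compared by this fit. Of 307 input windows 12 were called, 1 higher and 11 lower in the knockout, and 49 had an unadjusted p under 0.05. Of the lower ones 8 lay near 119.6 Mb of chromosome 13, nearest Ccl28, a chemokine gene, chosen after their values were seen. The strongest fell by 3.87 on the log2 scale (SE 0.34, edgeR adjusted p = 4.43e-05), from 37, 63 and 33 input tags to 4, 2 and 5 at chromosome 13, 119601616 to 119602616. A pair of overlapping windows nearest Col19a1 at 24.6 Mb of chromosome 1 held 88, 48 and 34 input tags in wild type and 4, 0 and 16 in the knockout, and 0 tags in all 6 H3K27ac libraries. Of the 12, 0 were among the 24 called H3K27ac windows, but nearly all of those 24 had too few input tags to enter this fit. The overlap therefore could not show whether input and H3K27ac differences coincide. Input calls moved with single libraries, from 12 to 6 and 4 without wild-type replicates 1 and 2, and to 5, 25 and 47 without knockout replicates 1, 2 and 3.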

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

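The tests in this part were all chosen only after the result was seen. Input chromatin stood outside the H3K27ac comparisons, yet input tags differed between genotypes in 6 of the 24 called H3K27ac windows (2-sided exact binomial test on tags summed over 3 libraries, which covers counting error only, adjusted over the 24 windows). At the Nlrp3 TSS window the knockout held 0 input tags and wild type 18 (exact test, adjusted p = 3.06e-05), and at the second Nlrp3 promoter window 3 and 16 (0.00883), so DNA of the targeted allele missing there was not separated from lost acetylation. At the G530011O06Rik window on chromosome X the knockout held 28 and wild type 61 (exact test, adjusted p = 8.07e-04), of which 29 were in wild-type replicate 1, the library without Y-linked tags. Without that library the H3K27ac call ended (−1.14, edgeR adjusted p = 0.446). It also ended without wild-type replicate 2, knockout replicate 1 or knockout replicate 2. Wild-type replicates 2 and 3 held 17 and 15 input tags there, and the knockout libraries 6, 8 and 14. The input ratio, knockout to wild type, was 0.408 (95% interval 0.251 to 0.648), close to the H3K27ac ratio of 0.388. This window also entered the input fit, with a log2 fold change of −1.40 (SE 0.46) that was not called. A lower amount of DNA there was therefore not separated from lower H3K27ac. The Rnf157 windows held 0 against 9 (0.00678) and 2 against 11 (0.0383). The window upstream of Slc1a3 went the other way, with 35 input tags in the knockout and 10 in wild type (exact test, adjusted p = 0.00668). Scaled to equal totals, input went the same way as H3K27ac in all called windows except those nearest Gaa (4 knockout against 5 wild-type tags) and Mir3086 (6 against 5). Most of these input differences did not pass the threshold. At the Eps8 and Me2 windows named above, input tags were 20 against 10 and 17 against 6.

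Windows that rose and windows that fell came from different site lists. The test of this left out called windows that stood in both lists (2 that rose, 4 that fell). It counted overlapping windows and both Nlrp3 promoter windows separately, so its p is approximate. Of the 10 that rose, 8 stood in the knockout list alone and 0 in the wild-type list alone, and of the 14 that fell, 0 and 10 (2-sided Fisher's exact p = 2.29e-05). For the called windows this is in line with accessible sites and H3K27ac moving the same way, but over all tested windows the lists hardly differed, with median log2 fold changes of 0.0017 (wild-type list alone), 0.033 (knockout list alone) and 0.0031 (both), and the sources used here do not say whether the lists came from the same animals. Lost or unmappable DNA in the knockout cannot be told apart from lower H3K27ac at most windows that fell, since single windows held few input tags. The test took 11 such windows outside Nlrp3, counting 1 of each overlapping pair. In 3 the 95% interval of the input ratio, knockout to wild type, lay above the H3K27ac ratio plus 2 SE. In 3 that interval lay under 1, of which 1 window met both, and 6 met neither. The window that met both, in Rnf157, held 0 knockout H3K27ac tags, so its fitted ratio has no firm bound. Its input interval began at 0.0174, close to the fitted H3K27ac bound of 0.0157, and the floor of 3 tags was not applied in this test. Its place among the first 3 is therefore not settled. A first form of this test, which summed tags over 12 windows (0.503 for input, 0.256 for H3K27ac), and a later one that parted the windows by their own input were set aside after their values were seen. A change of chromatin activity with genotype was not tested apart from these comparisons.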

How the results depend on the processing

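The fits without overlapping windows, on assembled chromosomes with more ChIP than input tags, without chromosomes X and Y (23 windows, 28 genes), and without the upstream Slc1a3 window were chosen only after the result was seen. The 24 called windows became 68 with DESeq2 (16 shared) and 68 without the abundance filter (24 shared), where the fit put its prior degrees of freedom at infinity and so took no spread from single windows, and 10 to 29 with 1 library left out; the other alternatives gave 21 to 25. The 25 called genes became 16 with total tags, 38 with DESeq2, 48 without the filter, 1 within 1 kb of a TSS and 8 to 18 with 1 library left out; other normalizations and other choices of windows gave 23 to 28. Called Nlrp3 windows became 1 with DESeq2 and 1 to 2 with 1 library left out. The promoter odds ratio passed the threshold with DESeq2 alone (0.456, Fisher's exact p = 0.00987), where more windows were called, and ran from 0.170 to 0.774 with 1 library left out. Called input windows became 34 without the filter and 4 to 47 with 1 library left out. Gene lists and the Nlrp3 flank kept 0 calls under every alternative run for them, which for the flank is likely at the called share elsewhere too. Replicate numbers did not pair the samples: deviations of equal-numbered libraries correlated at −5.98e-04 to 0.00329, and 2 of 6 libraries correlated best with the library of the same number in the other genotype. A replicate block gave 21 windows, 15 genes, 5 input windows and 0 lists, and ended the calls of the genes Slc1a3 (edgeR adjusted p = 0.0604), Mpc1 (0.0649) and Cd300c2 (0.0814) and of the windows nearest Tnfrsf14 (0.0924) and G530011O06Rik (0.129). Of 809 further values for named windows and genes 703 kept direction and side of the threshold, 81 lost their call, 1 gained it (Me2 without wild-type replicate 3, 1.95) and 24 turned sign, all of these in genes never called. With 1 library left out the log2 fold changes ran from −0.011 to 0.54 for Glud1, −0.15 to 0.031 for Il1b, −0.10 to 0.29 for Trem2, −1.40 to 0.24 for Spp1, −0.14 to 0.095 for Sall1, −8.6e-04 to 0.15 for P2ry12 and −0.19 to 0.25 for Apoe. Within 1 kb of a TSS they were −0.048 for Cd9, 0.28 for Kat7, 0.17 for Cnp, −0.21 for Glul, −0.052 for P2ry12 and −0.27 for Trem2, with total tags 0.0018 for Sall1, and on assembled chromosomes −0.0021 for Trem2. Except where stated, the cause was not tested. The planned motif test was not run.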

Other observations

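Among the tests in this part, the splits of the libraries for windows, genes and input were planned, and all others were chosen only after the result was seen. The called genes Cd300lf and Cd300c2, both myeloid receptors of the CD300 family near 115 Mb of chromosome 11, went in opposite directions, with log2 fold changes of 1.29 and −0.97. Both lie among the clustered loci between 109 and 119 Mb described below, where chromosome segments of another strain were not excluded.

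The 6 libraries can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 24 windows, and the highest of the other splits called 3. For genes the values were 25 and 0, and for input windows 12 and 0. In each of these 3 tests 1 split of 10, the real one, gave as many calls. For gene lists all 10 of the splits gave 0 calls.

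The windows with an unadjusted p under 0.001 lay near each other. The 94 windows formed 66 loci at least 200 kb apart, and 34 loci had another within 5 Mb, for example 9 loci between 109 and 119 Mb of chromosome 11 and 4 loci between 136 and 138 Mb of chromosome 6 that included Eps8. Of the 25 called genes 7 lay in or within 1 Mb of a run of at least 3 such loci, Eps8, Cd300lf and Cd300c2 among them. Of tested genes 2.55% lay there. The runs were drawn from the same libraries as the gene calls, so this share is no separate support. Random draws of 66 loci gave a median of 18 and a 95th percentile of 25 (permutation p = 9.99e-04, the smallest that 1000 draws can give), which argues against overlapping windows as the cause, since loci were thinned first. Regional variation that does not follow genotype and chromosome segments of another strain in the knockout line cannot be told apart: the highest of the other splits had 26 such loci and their SD was 4.19, and neighbouring loci shared a direction in 50% of 48 pairs (95% interval 35.2% to 64.8%). The pairs share loci, and most come from the 9 loci of chromosome 11. The interval treats them as independent and is therefore too narrow. An earlier form of the test compared 94 windows without equal numbers of loci and gave a random median of 33 and a highest other split of 39, and no genotypes were used here to read the strain.

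At Slc1a3, knockout replicates 1 and 3 held 434 and 458 tags in the upstream window and replicate 2 held 55. Astrocytes, which express Slc1a3 and which the CD11b selection would remove, cannot be told apart as a source: 15 astrocyte markers had median log2 differences from wild type of −0.18 in both libraries and −0.10 in replicate 2, but 9 of them lay under 5 CPM in wild type and 2 above 50 CPM, where a small share would not show. A weaker immunoprecipitation in replicate 2 is argued against by its share of tags in windows, 45.3% against 46.1% and 39.1%, and by the windows at the 3' end of the gene, at 83.5 CPM against 82.5 and 68.8, and other differences between preparations were not tested. Extra DNA copies may add to the signal and cannot be told apart from higher H3K27ac: input in the upstream window was 3.53 times wild type in replicate 1 (95% interval 1.56 to 8.50) and 4.25 times in replicate 3 (1.76 to 10.7), against 13.9 (10.98 to 17.7) and 13.5 (10.7 to 17.2) times for H3K27ac, and a comparison with windows of like H3K27ac count had only 13 and 11 windows to draw on.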
